A study of Homo sapiens with 4 samples.

How the data were processed

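RNA was taken from 4 samples of MM134 cells, 2 of the HER2 WT line and 2 of the HER2 L755S line, all deprived of estrogen. Per the labels' protocols, libraries were made from 250 ng of total RNA by poly(A) selection with a TruSeq kit and sequenced on a NovaSeq instrument. How HER2 was introduced or altered in the lines, and whether the libraries of a line came from separate cultures, is not given in the sources used here. The group and replicate number of each library were taken from its title.

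Per the file headers, each deposited gene table is RSEM output. It holds an expected count per gene, which is an estimated count that need not be whole, made by the authors. The deposited tables also hold TPM and FPKM values, computed by the authors from the same estimates per the file headers, and these were not tested. The submitters' processing notes name STAR, edgeR and the GRCh38 build, with no version and no role. The annotation release of the authors is not given in the sources used here. The names of the 2 deposited tables of replicate 2 carry the word merged, and what was merged is not stated. Between 9.53% and 11.5% of the genes in a library had an expected count that was not whole. RSEM divides reads that fit several genes among them, so values of paralogs such as IFITM2 and IFITM3 are uncertain. The strand setting is not given in the sources used here, so reads of overlapping antisense genes may be mixed.

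Expected counts were rounded to whole numbers. Of 60675 genes in the tables, 16538 passed filterByExpr of edgeR with the 2 groups. Libraries were scaled with TMM, with factors from 0.937 to 1.04. The lines were compared with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with no term for the replicate number, and p-values were adjusted by Benjamini-Hochberg over the tested genes at a threshold of 0.05. Fold changes are HER2 L755S over HER2 WT. Differences within a pair are on the scale of log2 CPM with a prior count of 0.5, while CPM values have no prior count. CPM values of tested genes use library totals multiplied by the TMM factor. The total expected count per library was 27423259 to 31088398.

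The 33 gene lists, with 891 symbols matched to 877 genes, were tested as sets with camera in limma 3.58.1, with a preset correlation of 0.01, where at least 5 members were tested, which left 32 lists. Among them are markers of leukocytes and of fibroblasts and endothelium, and 2 lists on RNA quality. The named genes are a fixed group of receptor and lineage genes, the 10 higher and 10 lower genes with the largest log2 fold change among called genes with at least 5 CPM in the higher group, no overlap between the groups and a symbol, and up to 4 members of each described list by adjusted p. Other genes named in the text were chosen after their values were seen. The tests, lists, naming rule and most alternatives were set before the data were examined.

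The test was tried on simulated counts for the comparison of the lines, drawn for 16538 genes from the means and library sizes of these samples. It recovered 12% of genes changed 2-fold, 70% of those changed 4-fold, 90% of those changed 8-fold and 100% of those changed 16-fold, and 9 of its calls (6.16%) were false. In this fit, without a term for the replicate number, most differences of 2-fold would thus be missed. For a simulated list of 40 genes shifted by 0.8 on the log2 scale, camera gave p = 9.49e-19 with the preset correlation and 0.0239 with an estimated one. The simulated genes were drawn independently, whereas the correlations estimated for the called lists ran from 0.039 to 0.66. These p-values therefore do not show why real lists lost their calls with an estimated correlation.

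Alternatives were size factors of DESeq2 in edgeR, no scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, an adjusted p of 0.01, glmTreat against a fold of 1.5, leaving out each library, and for lists an estimated correlation, fry and ranks with cameraPR. A run without genes of chromosomes 1, 8 and 11 and another without mitochondrial genes were added after the data were seen. Gene positions are from GENCODE 29 on GRCh38, in which 16426 of the tested genes were found by Ensembl identifier. Chromosome medians used 10823 protein-coding genes of at least 5 CPM on average, and windows of 5 Mb with at least 10 such genes.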

Results

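Gene expression was measured by RNA sequencing in MM134 cells, an estrogen receptor positive line derived from an invasive lobular breast carcinoma. One line carried wild-type HER2, the receptor tyrosine kinase encoded by ERBB2, and the other carried HER2 L755S, a substitution in the kinase domain. Both lines had been deprived of estrogen for 7 days in medium with 5% charcoal-stripped serum, after growth to 70% confluence. Each line was represented by 2 libraries, HER2 WT 1 and 2 and HER2 L755S 1 and 2. The total expected count was 31088398 in HER2 WT 1 and 28836397 in HER2 L755S 1. It was 28804785 in HER2 WT 2 and 27423259 in HER2 L755S 2. Because the labels do not say that the 2 libraries of a line came from separate cultures, the p-values below measure only the spread between these libraries, which may be technical. Where 1 library was left out, the spread of its line was not measured and was taken from the other line. A call gained in such a fit is therefore no added support for a difference.

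Libraries that shared a replicate number also shared features unrelated to the line. Mitochondrial transcripts took 4.395% of the counts in HER2 WT 1 and 4.03% in HER2 L755S 1, against 8.83% in HER2 WT 2 and 13.5% in HER2 L755S 2. The immediate early gene EGR1 stood at 98.6 and 243 CPM (counts scaled to the library total) in HER2 WT 1 and HER2 L755S 1 and at 5.65 and 34.7 CPM in HER2 WT 2 and HER2 L755S 2. FOS, another immediate early gene, stood at 108 and 52.5 CPM in the number 1 libraries and at 12.9 and 11.6 CPM in the number 2 libraries. Differences between the lines are therefore also given within each number, as pair 1 (HER2 L755S 1 over HER2 WT 1) and pair 2 (HER2 L755S 2 over HER2 WT 2).

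The design asks how the transcriptome of estrogen-deprived cells differed between the 2 HER2 lines. Among genes that were higher in HER2 L755S than in HER2 WT cells were HMGCS1 and SCD of lipid synthesis, the interferon-stimulated genes IFIT2 and ISG15, and SPRY1, SPRED1 and SPRY4, which encode inhibitors of MAPK signalling. Among those that were lower were HLA-DRA and CD74 of MHC class II, the interferon-stimulated genes IFITM2 and IFITM3, and the estrogen receptor targets ELOVL2, SUSD3 and SGK3. The largest increase among named genes was that of POSTN, which encodes the matrix protein periostin. It rose from 0.0998 ± 0.0537 to 24.7 ± 0.421 CPM (mean ± SD, n = 2). The largest decrease among them was that of the mucin gene MUC5B, from 21.4 ± 7.00 to 0.456 ± 0.370 CPM (n = 2), with 0.718 CPM left in HER2 L755S 1 and 0.195 CPM in HER2 L755S 2. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 122 of 16538 tested genes were higher and 157 were lower in HER2 L755S cells at an adjusted p under 0.05. Of these, 95 higher and 132 lower genes differed by more than 4-fold. All 279 called genes had no overlap between the lines, so the same direction in both pairs follows from that and is no separate support.

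ERBB2 itself (ENSG00000141736, GRCh38 chromosome 17, 39687914 to 39730426) did not differ between the lines beyond the spread of the libraries. Its level was 1930 and 1940 CPM in HER2 WT 1 and 2, and 2440 and 1200 CPM in HER2 L755S 1 and 2. The log2 fold change was -0.09 (SE 0.35), with 0.34 in pair 1 and -0.69 in pair 2 (edgeR, Benjamini-Hochberg adjusted p = 1). Without HER2 L755S 2 the log2 fold change of ERBB2 was 0.33, within a range of -0.69 to 0.33 over all alternatives. The HER2 partner ERBB3 averaged 444 ± 102 CPM in HER2 WT and 394 ± 11.7 CPM in HER2 L755S cells (n = 2), and its log2 fold change was -0.18 in all 4 libraries and 0.10 without HER2 WT 2. ERBB4 stood at 0.666 ± 0.456 and 2.63 ± 0.963 CPM (adjusted p = 0.18), and was called without HER2 WT 1 or HER2 L755S 1 (adjusted p = 0.041 and 0.027, in a range from 0.019 to 0.63). EGFR, with 1 and 0 counts in HER2 WT and 3 and 0 in HER2 L755S libraries, was too low to test.

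Genes of the luminal and estrogen receptor axis had mixed values, and in the fit of all 4 libraries, with no term for the replicate number, none of those chosen singly in advance (ESR1, GREB1, TFF1, GATA3, FOXA1, CDH1, FGFR1, CCND1 and BCL2) passed the threshold. ESR1, the gene of the estrogen receptor, averaged 229 ± 74.5 CPM in HER2 WT and 93.5 ± 40.8 CPM in HER2 L755S cells (n = 2). Its log2 fold change was -1.29 (SE 0.38), with -1.45 in pair 1 and -1.20 in pair 2 (edgeR, Benjamini-Hochberg adjusted p = 0.15). With the replicate number as a block ESR1 was called (edgeR, adjusted p = 0.00017). Over the alternatives its log2 fold change ranged from -1.83 to -0.89 and its adjusted p reached 0.61. CCND1, which encodes cyclin D1, averaged 6800 ± 308 and 2990 ± 512 CPM, a log2 fold change of -1.19 (pairs -0.98 and -1.42, adjusted p = 0.066, range 0.0013 to 0.25). CCND1 was called without HER2 WT 1, HER2 L755S 1 or HER2 L755S 2 (adjusted p = 0.022, 0.0015 and 0.014). FGFR1 (chromosome 8, 38400215 to 38468834), a growth factor receptor, averaged 4290 ± 94.2 and 2020 ± 310 CPM, a log2 fold change of -1.09 (pairs -0.92 and -1.28, adjusted p = 0.094, range 0.0042 to 0.37), and was called without HER2 L755S 1 (adjusted p = 0.012). BCL2, an inhibitor of apoptosis, stood at 90.4 ± 28.5 and 48.9 ± 10.6 CPM (pairs -0.76 and -0.97, adjusted p = 0.35, range 0.0054 to 1). The log2 fold change was -0.58 for the estrogen-induced gene GREB1, 0.81 for TFF1, 0.39 for the luminal factor GATA3, 0.30 for FOXA1 and -0.17 for the cadherin gene CDH1. For CDH1 it was 0.09 without HER2 L755S 2. The progesterone receptor gene PGR had 7 and 16 counts in HER2 WT and 2 and 0 in HER2 L755S libraries, too few to test. CCND1, FGFR1 and BCL2 were also called with the replicate number as a block (edgeR, adjusted p = 0.0028, 0.0042 and 0.0054). The labels do not say what that number stands for. FGFR1 and CCND1 lie on chromosomes 8 and 11, on which most genes were lower in HER2 L755S cells, as described at the end.

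**Figure D1:**
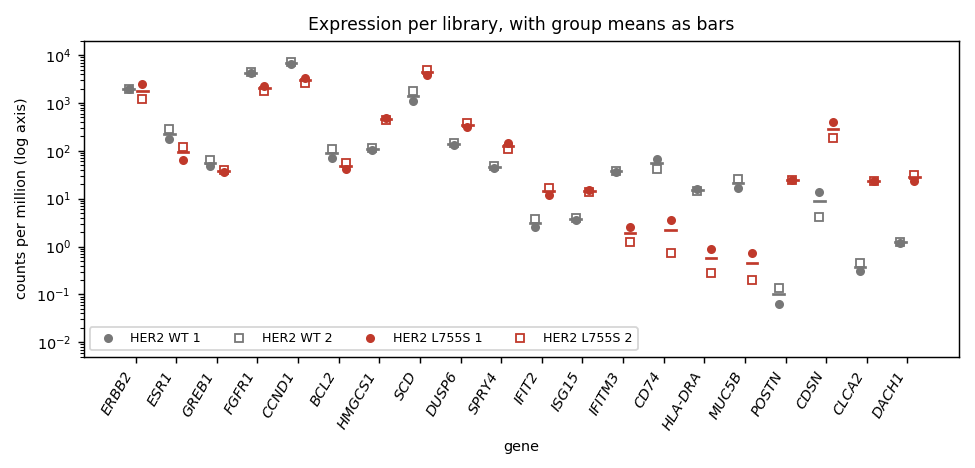
Expression of 20 genes in CPM (log axis) in each of the 4 libraries, with HER2 WT in grey and HER2 L755S in red, filled circles for number 1, open squares for number 2 and a bar at the mean of each group. ERBB2 overlapped between the lines, while POSTN averaged 0.0998 CPM in HER2 WT and 24.7 CPM in HER2 L755S libraries.

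Among called genes with at least 5 CPM in the higher group, the 10 with the largest increase were POSTN, HSD17B2, CLCA2, ABCA12, ABCC4, CDSN, ROBO2, DACH1, FAM131B and NR2F1. POSTN (ENSG00000133110, chromosome 13, 37562583 to 37598844) had a log2 fold change of 7.91 (SE 0.54), with 8.27 in pair 1 and 7.34 in pair 2 (edgeR, Benjamini-Hochberg adjusted p = 0.00021). HSD17B2, an enzyme that oxidizes estradiol to estrone, rose by 6.12 (SE 0.70, pairs 6.52 and 5.05, adjusted p = 0.003), and its level was 72.7 CPM in HER2 L755S 1 and 17.6 CPM in HER2 L755S 2. CDSN, which encodes the epidermal adhesion protein corneodesmosin, reached the highest level of the 10 genes, at 291 ± 144 CPM against 9.02 ± 6.82 CPM (log2 5.01, SE 0.60). CLCA2 rose by 5.95 on the log2 scale, the lipid transporter gene ABCA12 by 5.49, the efflux transporter gene ABCC4 by 5.35 and the guidance receptor gene ROBO2 by 4.70. The transcription factor genes DACH1 and NR2F1 rose by 4.50 and 3.93.

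Among called genes with at least 5 CPM in the higher group, the 10 with the largest decrease were MUC5B, NSMAF, TSPAN6, NPNT, PHYHD1, HLA-DRA, BARX2, CD74, ME3 and ASRGL1. MUC5B (ENSG00000117983, chromosome 11, 1223066 to 1262172) had a log2 fold change of -5.51 (SE 0.59), with -4.48 in pair 1 and -6.96 in pair 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0022). TSPAN6 fell by 4.82, the integrin ligand gene NPNT by 4.78 and the homeobox gene BARX2 by 4.62 on the log2 scale. NSMAF, ME3 and ASRGL1 were nearly absent from HER2 L755S 2, at 0, 0 and 0.0389 CPM, and stood at 0.479, 0.410 and 2.12 CPM in HER2 L755S 1. The size of their log2 fold changes (-5.02, -4.58 and -4.51) therefore depends on HER2 L755S 1, without which at most 1 count of each gene is left in the line. They were the 3 of these 20 genes that DESeq2 did not call, with adjusted p = 0.27, 0.31 and 0.26, and over all alternatives the adjusted p of the 20 genes ranged from 2e-33 to 0.31.

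Leaving out 1 library raised the number of calls, although the spread of its line was then not measured. Higher genes numbered 192 without HER2 WT 1, 214 without HER2 L755S 1 and 220 without HER2 L755S 2, and lower genes numbered 328 without HER2 L755S 1. In the 4 libraries, 36.2% of tested genes had no overlap between the lines. Chance gives 33.3% only if every order of the 4 libraries is equally likely. Same-numbered libraries shared differences, so that condition was not met and the 2 shares cannot be compared.

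**Figure D2:**
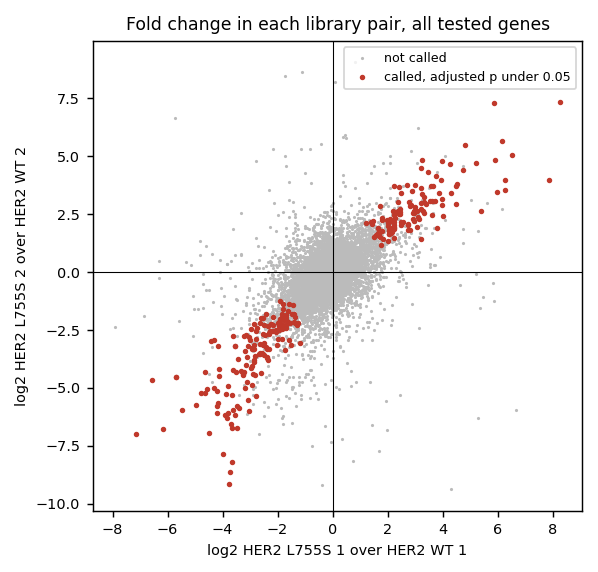
Log2 fold change of each tested gene in pair 1 (x axis) and in pair 2 (y axis), with the 279 called genes in red and the others in grey. All called genes lie in the quadrants where both pairs have the same sign, which follows from their lack of overlap between the lines.

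HMGCS1 and STARD4 were the called members of the cholesterol synthesis list, both higher in HER2 L755S cells. HMGCS1, the synthase that makes the HMG-CoA used by the pathway, rose from 109 ± 10.5 to 464 ± 21.8 CPM (n = 2, log2 2.08, SE 0.30, pairs 2.23 and 1.94, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0067). The sterol carrier gene STARD4 rose from 0.626 ± 0.186 to 7.91 ± 0.548 CPM (log2 3.66, SE 0.48). Of 26 tested members, 2 were called over all genes and 7 adjusted over the list alone, all higher, and 21 had a positive log2 fold change. MSMO1 and INSIG1 had log2 fold changes of 1.34 and 1.31 (adjusted p = 0.06 and 0.062), and without HER2 L755S 1 that of INSIG1 was called (adjusted p = 0.045, range 0.00026 to 0.3). The median of the list was 0.62, with 0.59 in pair 1 and 0.51 in pair 2. Camera with a preset correlation called the list higher (adjusted p = 9.2e-10), and the call was lost at adjusted p = 0.69 with an estimated correlation, the highest of a range from 3.7e-12 over the alternatives.

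The called member of the fatty acid and triglyceride synthesis list was SCD. This gene, which desaturates stearate, rose from 1430 ± 492 to 4350 ± 659 CPM (n = 2, log2 1.61, SE 0.33, pairs 1.85 and 1.44, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.035). It was the 1 called gene of 24 over all genes, and 4 were called adjusted over the list alone, all higher. ACSL1, FASN and ACSL3 had log2 fold changes of 1.45, 1.47 and 0.99 and did not pass (adjusted p = 0.053, 0.13 and 0.16). ACSL1 was called without HER2 L755S 2 (adjusted p = 0.034, range 0.00013 to 0.23) and FASN without HER2 WT 1 or HER2 L755S 2 (0.0042 and 1.8e-06, with 0.53 the highest). Camera gave adjusted p = 0.0011 for the list (median 0.32, pairs 0.61 and 0.26). It gave adjusted p = 0.69 with an estimated correlation and 0.096 without HER2 L755S 1, in a range from 8.1e-06 to 0.69.

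The called members of the MAPK output list were SPRY1, SPRED1 and SPRY4. SPRY1 rose from 0.682 ± 0.0398 to 6.35 ± 3.69 CPM (n = 2, log2 3.21, SE 0.55, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.015). SPRED1 rose by 1.82 (pairs 1.67 and 1.91) and SPRY4 by 1.47 (pairs 1.75 and 1.17). The ERK phosphatase gene DUSP6 averaged 142 ± 9.47 and 348 ± 46.4 CPM, with a log2 fold change of 1.30 (adjusted p = 0.06, and 0.032 without HER2 L755S 1, in a range from 0.00025 to 0.24). Of 23 tested members, 3 were called over all genes, all higher, and adjusted over the list alone 4 were higher and 1 was lower. The list had a median of 0.29, with 0.30 in pair 1 and 0.01 in pair 2. Camera gave adjusted p = 0.027 for the list, which became adjusted p = 0.69 with an estimated correlation, 0.077 without HER2 L755S 1, 0.063 without HER2 WT 2 and 0.27 on ranks, in a range from 0.00041 to 0.69. SPRED1 lost its call without HER2 WT 1 or HER2 L755S 2 (adjusted p = 0.11 and 0.15). SPRY4 lost its call without HER2 WT 1, HER2 L755S 1 or HER2 WT 2 (0.18, 0.16 and 0.089) and with no scaling (0.072), and the 3 genes ranged from 1.7e-07 to 0.18 over the alternatives.

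In the interferon response list 5 members rose and 2 fell. IFIT2 rose from 3.14 ± 0.770 to 14.3 ± 2.97 CPM (n = 2, log2 2.19, SE 0.40, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.022), and the ubiquitin-like modifier gene ISG15 rose from 3.77 ± 0.312 to 14.7 ± 1.14 CPM (log2 1.96, adjusted p = 0.026). The other higher members were IFI6, IFIT1 and IFIT5, with log2 fold changes of 1.90, 2.49 and 2.17. IFITM3, a membrane protein that restricts virus entry, fell from 37.0 ± 1.13 to 1.91 ± 0.932 CPM (log2 -4.27, pairs -3.81 and -4.90), and its neighbour IFITM2 had a log2 fold change of -4.23. These paralogs have near-identical sequences, and the counting could have divided shared reads between them. Of 37 tested members, 5 were called higher and 2 lower over all genes, and 10 higher and 2 lower adjusted over the list alone. Camera called the list higher (adjusted p = 1.1e-04, median 0.44, pairs 0.62 and 0.45), at adjusted p = 0.69 with an estimated correlation, in a range from 1.3e-07.

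The called members of the antigen presentation list were MHC class II genes, all lower. HLA-DRA fell from 15.4 ± 0.982 to 0.581 ± 0.436 CPM (n = 2, log2 -4.70, SE 0.55, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0033) and CD74, the class II invariant chain, from 54.3 ± 18.0 to 2.20 ± 2.06 CPM (log2 -4.61, SE 0.64). In HER2 L755S 1 and 2, HLA-DRA stood at 0.889 and 0.273 CPM and CD74 at 3.66 and 0.740 CPM. HLA-DMA, which helps load peptides on class II molecules, fell by 2.41. HLA-DMB had 47 counts in the HER2 WT libraries and 1 in the HER2 L755S libraries, a ratio of 44.1 (95% interval 7.55 to 1780, counting error only), and lost its call with DESeq2 (adjusted p = 0.081) and without HER2 WT 1 or HER2 L755S 2 (0.21 and 0.089, in a range from 0.0011). CIITA, the activator of class II transcription, averaged 2.13 and 0.454 CPM (adjusted p = 0.079). Of 20 tested members, 4 were called over all genes and 6 adjusted over the list alone, all lower. The median of the list was -0.17 (pairs -0.07 and -0.29) and its mean was -1.08. Camera gave adjusted p = 2.7e-04 for the list, which became adjusted p = 0.69 with an estimated correlation and 0.37 on ranks, in a range from 1.5e-05 to 0.69.

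Of the estrogen receptor targets, 3 fell and 1 rose. ELOVL2, a fatty acid elongase, fell from 59.2 ± 11.4 to 17.1 ± 1.85 CPM (n = 2, log2 -1.79, SE 0.34, pairs -1.70 and -1.87, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.026). SUSD3 fell by 1.72 and the kinase gene SGK3 by 1.96, while the secreted disulfide isomerase gene AGR2 rose by 2.24. SGK3 lies on chromosome 8 (66667596 to 66862022), in a 5 Mb window whose genes had a median of -0.85 relative to the other chromosomes (pairs -0.81 and -1.08). Of 41 tested members, 1 was called higher and 3 lower over all genes, 1 higher and 8 lower adjusted over the list alone, and 32 had a negative log2 fold change. Camera called the list lower (adjusted p = 1.1e-04, median -0.50, pairs -0.31 and -0.62), at adjusted p = 0.69 with an estimated correlation, in a range from 3.4e-06. ELOVL2 and SGK3 lost their calls without HER2 L755S 1 (adjusted p = 0.069 and 0.06) and without HER2 WT 2 (0.053 and 0.072). SUSD3 lost its call without HER2 WT 1 or HER2 L755S 2 (0.065 and 0.091) and AGR2 without HER2 WT 1 (0.055), and the 4 genes ranged from 1.1e-05 to 0.091.

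The G2-M and mitosis list differed by pair. Its median log2 fold change was -0.52 in all 4 libraries, -1.15 in pair 1 and 0.02 in pair 2, so the difference did not hold within both numbers. CDC20, an activator of the anaphase-promoting complex, stood at 124 and 60.3 CPM in HER2 WT 1 and 2 and at 37.8 and 44.2 CPM in HER2 L755S 1 and 2. The mitotic kinase gene PLK1 stood at 87.1 and 35.7 CPM in HER2 WT and at 26.2 and 30.3 CPM in HER2 L755S libraries. Without HER2 WT 2, CDC20 and PLK1 were called (adjusted p = 0.036 and 0.037), and without HER2 WT 1 they had adjusted p = 0.93 and 1, the highest of ranges from 0.0085 and 0.024. Of 40 tested members, edgeR, DESeq2 and limma-voom each called 0 with no term for the replicate number. EdgeR then called 0 adjusted over the list alone, with 4 lower at an unadjusted p under 0.05. With the replicate number as a block edgeR called 9 lower and 0 higher, among them CDC20, KIF2C, PLK1 and CENPF (adjusted p = 0.0085, 0.0085, 0.024 and 0.002). Camera gave adjusted p = 1.5e-05 for the list, adjusted p = 0.73 with an estimated correlation and 0.65 without HER2 L755S 1, in a range from 5e-18 to 0.73.

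The remaining lists called by camera were the ATF4 and amino acid response and nuclear oxidative phosphorylation, which lost their calls at adjusted p = 0.73 and 0.69 with an estimated correlation. The cystine transporter gene SLC7A11 rose from 7.36 ± 1.69 to 29.5 ± 13 CPM (n = 2, log2 2.00, SE 0.41, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.036), and lost its call without HER2 L755S 1 or HER2 WT 2 and with no scaling (adjusted p = 0.085, 0.056 and 0.052, in a range from 1.5e-05). It was the 1 called of 28 members over all genes, and 8 were higher and 2 lower adjusted over the list alone. NUPR1 had a log2 fold change of 3.86 (pairs 3.78 and 4.33, adjusted p = 0.057, at most 0.2 over the alternatives). It stood at 2.97 and 0.379 CPM in HER2 WT 1 and 2. STC2, with a log2 fold change of -2.05 (adjusted p = 0.053, range 1.5e-05 to 0.14), was called lower without HER2 WT 1 or HER2 L755S 1 (3e-05 and 0.00045). DDIT4, with 1.53 (adjusted p = 0.089, range 4.2e-05 to 0.34), was called higher without HER2 WT 1 or HER2 L755S 2 (0.012 and 0.0025). The ATF4 list (median 0.52, pairs 0.64 and 0.46) had camera adjusted p = 1.8e-04, and 0.35 without HER2 L755S 1, in a range from 2.4e-14 to 0.73. Of 36 nuclear oxidative phosphorylation genes, edgeR, DESeq2 and limma-voom each called 0, and edgeR called 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. With the replicate number as a block edgeR called 2 higher and 1 lower. COX7B, NDUFA4 and NDUFV1 had log2 fold changes of 1.00, 0.70 and -0.83. Without HER2 L755S 1, COX7B was called higher (adjusted p = 0.05, in a range from 0.0054 to 1) and NDUFV1 lower (0.041, in a range from 0.012 to 1). That list (median 0.27, pairs 0.16 and 0.39) had camera adjusted p = 0.03, and 0.074, 0.21 and 0.12 without HER2 L755S 1, HER2 WT 2 and HER2 L755S 2, in a range from 0.002 to 0.69. The 15 mitochondrially encoded transcripts had a median of -0.14 in pair 1 and 0.77 in pair 2.

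**Figure D3:**
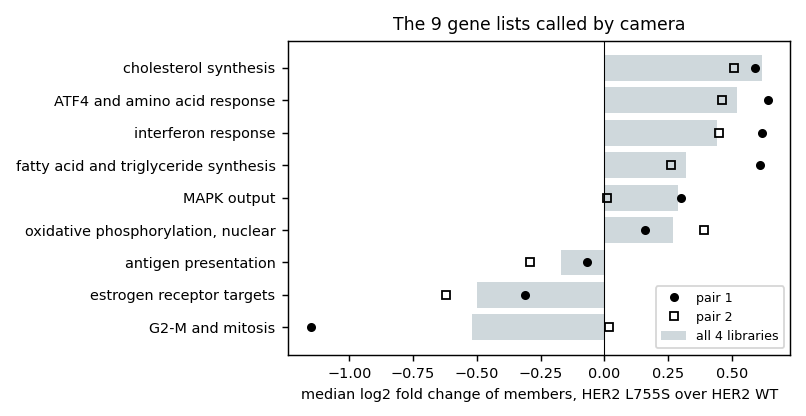
Median log2 fold change of the tested members of the 9 gene lists called by camera, as bars for all 4 libraries, filled circles for pair 1 and open squares for pair 2. The G2-M and mitosis list had a median of -1.15 in pair 1 and 0.02 in pair 2, while cholesterol synthesis had 0.59 and 0.51.

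The other 24 lists were not called by camera, with adjusted p from 0.066 to 0.92 for the 23 that had at least 5 tested members. In 8 of them edgeR called single genes with Benjamini-Hochberg adjustment. In the mesenchymal list (camera adjusted p = 0.088) POSTN and the collagen gene COL5A1 were higher, 2 of 19 members over all genes and 3 adjusted over the list alone. Among FOXO targets and PI3K feedback genes (0.75) TRIB2 and KLF9 were higher and TXNIP was lower, with 3 higher and 2 lower adjusted over the list alone. Androgen and glucocorticoid receptor targets (0.086) had ABCC4 and KLF9 higher, with 3 higher and 2 lower adjusted over the list alone. Glycolysis and hypoxia (0.066) had PFKP higher, which lost its call without HER2 L755S 1 or HER2 WT 2 (adjusted p = 0.11 and 0.069), with limma-voom (0.058) and with no scaling (0.067), in a range from 0.00011, and 4 higher and 1 lower adjusted over the list alone. Luminal identity (0.60) had AGR2 higher and 1 higher and 3 lower adjusted over the list alone. Integrins and matrix (0.086) had the laminin gene LAMB1 lower (log2 -2.93) and 1 higher and 4 lower adjusted over the list alone, and cell adhesion (0.66) had the catenin gene CTNNA2 lower (log2 -4.10, with 0.376 and 0.0389 CPM in HER2 L755S 1 and 2) and 1 adjusted over the list alone. Of the 15 tested neighbours of ERBB2 at 17q12 (0.60), PPP1R1B was lower (log2 -1.59), the 1 call adjusted over the list alone, and it lost its call without HER2 WT 1, HER2 L755S 1 or HER2 L755S 2 (0.10, 0.13 and 0.085, in a range from 7.2e-05). Camera called 4 of these 8 lists without 1 library. They were the mesenchymal list without HER2 L755S 1 or HER2 WT 2 (adjusted p = 0.011 and 0.0014, with 0.95 the highest alternative), glycolysis and hypoxia without HER2 WT 1 or HER2 L755S 2 (0.049 and 0.00064, highest 0.77), androgen and glucocorticoid receptor targets without the same libraries (0.032 and 0.0066, highest 0.73) and integrins and matrix without HER2 WT 1 (0.036, highest 0.73).

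In the remaining 16 lists edgeR called 0 genes over all genes, limma-voom called 0 and DESeq2 called 5, and 0 to 4 genes a list had an unadjusted p under 0.05. Adjusted over the list alone, 9 genes were called in these lists, namely 1 higher and 3 lower in the neuronal and neuroendocrine list, 1 higher and 2 lower among FGF receptors and ligands, and 1 lower each among NF-kB and inflammatory cytokines and fibroblast and endothelial markers. The camera adjusted p was 0.086 for ERBB receptors and ligands, for ribosomal proteins and for mitochondrial transcripts, 0.13 for the unfolded protein response and 0.17 for p53 targets. It was 0.22 for basal and myoepithelial genes, 0.36 for G1-S and E2F targets and for neuronal and neuroendocrine genes, and 0.43 for MYC targets and ribosome biogenesis. It was 0.69 for apoptosis regulators and for transcripts without poly(A), 0.71 for immediate early and AP-1 genes and for NF-kB and inflammatory cytokines, 0.86 for fibroblast and endothelial markers and 0.92 for FGF receptors and ligands. Of these, immediate early and AP-1 genes were called higher or lower depending on the library left out, with adjusted p = 3.4e-06 without HER2 WT 1, 0.0011 without HER2 L755S 2 and 0.0036 in the other direction without HER2 WT 2. Mitochondrial transcripts had 2.9e-16 without HER2 L755S 1, 4.9e-08 without HER2 WT 2 and 6.5e-05 in the other direction without HER2 L755S 2, and ribosomal proteins had 0.0084 without HER2 WT 1. The highest values over the alternatives were 0.95, 0.79 and 0.77 for these 3 lists. Of the leukocyte markers 4 were tested, too few for camera. The median and the mean differed in sign for luminal identity (0.18 and -0.07), cell adhesion (0.03 and -0.19), androgen and glucocorticoid receptor targets (-0.01 and 0.43), neuronal and neuroendocrine genes (0.09 and -0.17), FGF receptors and ligands (-0.19 and 0.09), fibroblast and endothelial markers (0.19 and -0.35) and transcripts without poly(A) (-0.06 and 0.10). The test's direction followed the mean in these lists, except in luminal identity and among FGF receptors and ligands, where it followed the median.

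Genes on chromosomes 1, 8 and 11 had medians below those of the other chromosomes, in a comparison made after this difference was seen. Among 10823 protein-coding genes, the median log2 fold change relative to the other chromosomes was -0.42 on chromosome 8, with -0.48 in pair 1 and -0.40 in pair 2. It was -0.31 on chromosome 11 (pairs -0.33 and -0.32) and -0.25 on chromosome 1 (pairs -0.22 and -0.29). The other 20 chromosomes lay between -0.07 and 0.09. On chromosome 8, 81.7% of the genes lay below the median of the other chromosomes. The 5 Mb window with FGFR1 had a median of -0.81 (pairs -0.81 and -0.92), and the window with CCND1 one of -0.18 (pairs -0.29 and -0.06). Among the other genes named, SGK3 and NSMAF lie on chromosome 8, MUC5B, BARX2, ME3, ASRGL1, IFITM2, IFITM3 and NDUFV1 on chromosome 11, and TXNIP, CDC20, CLCA2, ISG15 and IFI6 on chromosome 1. On chromosome 11 the genes beyond 85 Mb, where BARX2 and ME3 lie, had a median of 0, and those before it one of -0.42. With camera over chromosomes, chromosomes 8, 11 and 1 were lower (Benjamini-Hochberg adjusted p = 4.3e-08, 2.1e-06 and 0.0016) and chromosome 21 higher (0.029). The values were adjusted p = 0.45, 0.77, 0.54 and 0.45 with an estimated correlation. These 3 chromosomes held 18.5% of the tested genes. They held 49 of the 156 lower genes with a position (31.4%, Fisher's exact test, two-sided p = 1.1e-04) and 14 of the 122 higher genes (11.5%, p = 0.046). The 3 chromosomes were picked for their low medians, and Fisher's test treats genes as independent, so neither p-value is separate support. Lower and higher calls numbered 18 and 13 of 1655 tested genes on chromosome 1, 11 and 0 of 527 on chromosome 8, and 20 and 1 of 865 on chromosome 11. Chromosome X, with a median of 0, had 17 lower and 4 higher calls among 503 tested genes.

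**Figure D4:**
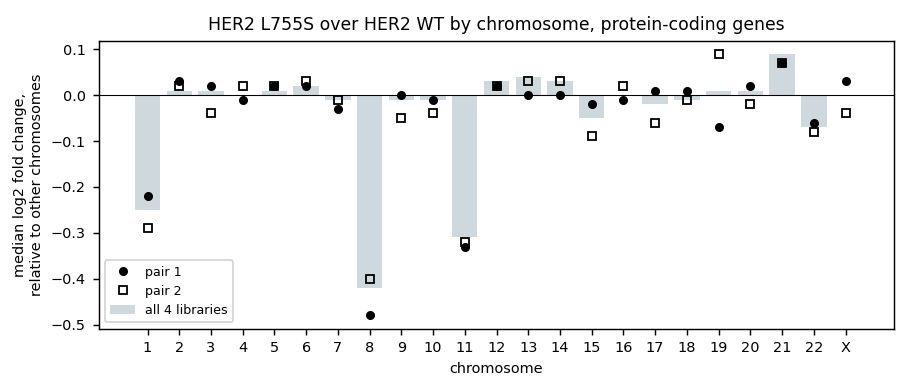
Median log2 fold change of protein-coding genes on each chromosome, relative to the other chromosomes, as bars for all 4 libraries, filled circles for pair 1 and open squares for pair 2. Chromosomes 8, 11 and 1 stand at -0.42, -0.31 and -0.25, and the others between -0.07 and 0.09.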

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

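The runs without genes of chromosomes 1, 8 and 11 and without mitochondrial genes were chosen after seeing the data. The counts of 122 higher and 157 lower genes became 133 and 159 with DESeq2 size factors, 104 and 157 with no scaling, 122 and 156 with limma-voom and 276 and 309 with DESeq2. They were 328 and 431 with no filter, 49 and 49 at an adjusted p of 0.01, and 75 and 87 with glmTreat against a fold of 1.5. Leaving out 1 library, with the lone library of a line assumed to vary like the other line, gave 160 to 220 higher and 184 to 328 lower genes. The causes were not tested. Of 45 called named genes, 14 lost their call with glmTreat and 22 at an adjusted p of 0.01. A stricter threshold cannot turn a fold change, and all 279 called genes had no overlap between the lines. That 0 of the 45 changed direction in these runs is therefore no separate support. With the replicate number as a block (replicate block) 725 genes were higher and 1018 lower. ESR1, CCND1, FGFR1, BCL2 and ERBB4 were then called (adjusted p = 0.00017, 0.0028, 0.0042, 0.0054 and 0.026). The labels do not say what a number stands for, and the deviations of same-numbered libraries correlated at 0.425. In that fit 3010 genes were called between the numbers. The relative spread between libraries that edgeR estimated was 0.299 without the block and 0.172 with it. The 9 called lists became 14 with no filter, 14 without genes of chromosomes 1, 8 and 11, 6 to 14 without 1 library, and 0 with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (3 at an unadjusted p). Fry asks whether a list moves one way on balance, not whether it differs from other genes, and its test for change in either direction called 18 lists.

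With an estimated correlation the adjusted p was 0.69 for estrogen receptor targets, MAPK output, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, interferon response and antigen presentation, and 0.73 for G2-M and for ATF4. The estimates rest on 4 libraries. They ran from 0.039 for estrogen receptor targets and oxidative phosphorylation, through 0.14 for cholesterol synthesis, to 0.66 for G2-M, against the preset 0.01. With fry it was 0.41 for estrogen receptor targets, cholesterol synthesis, oxidative phosphorylation, interferon response and antigen presentation, 0.43 for MAPK output and fatty acid synthesis, and 0.57 for G2-M and ATF4. On ranks (cameraPR) it was 0.27 for MAPK output and 0.37 for antigen presentation. Ranks called 12 lists and the replicate block 13. With the block edgeR called 13 cholesterol synthesis genes higher and 0 lower, and 10 fatty acid synthesis genes higher and 1 lower. It called 16 interferon response genes higher and 4 lower, 11 ATF4 genes higher and 2 lower, and 6 MAPK output genes higher and 1 lower. Of estrogen receptor targets 2 were then higher and 14 lower, and of antigen presentation genes 2 were higher and 7 lower. Among lists that camera did not call in the main fit, ribosomal proteins had adjusted p 0.003 on ranks and 0.048 with the block, mitochondrial transcripts 4e-04 and 0.023, and glycolysis and hypoxia 0.036 and 0.026. ERBB receptors and ligands and the unfolded protein response had 0.05 each on ranks, and integrins and matrix 0.048 with the block. Without 1 library it ranged from 0.00041 to 0.077 for MAPK output, 5e-18 to 0.65 for G2-M, 8.1e-06 to 0.096 for fatty acid synthesis, 0.016 to 0.21 for oxidative phosphorylation and 2.4e-14 to 0.35 for ATF4. The direction turned without 1 library for lists and genes that were not called, namely immediate early and AP-1 genes (adjusted p 3.4e-06 to 0.24), mitochondrial transcripts (2.9e-16 to 0.73), ERBB2 (log2 -0.69 to 0.33), ERBB3 (-0.40 to 0.10) and CDH1 (-0.50 to 0.09). The 9 called lists kept their direction in all alternatives. With 1 count of HLA-DMB in the HER2 L755S libraries against 47 in the HER2 WT libraries, depth leaves the interval of its ratio at 7.55 to 1780.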

Other observations

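Several abundant genes outside the fixed lists also differed between the lines, and they were named after their values were seen. With edgeR and Benjamini-Hochberg adjustment, the membrane protein gene TM4SF1 rose from 331 ± 2.91 to 1510 ± 178 CPM (n = 2, log2 2.19, adjusted p = 0.0055), the calcium-binding protein gene S100A6 from 90.7 ± 22.7 to 483 ± 43.8 CPM (log2 2.41, adjusted p = 0.0052) and the peroxisomal oxidase gene ACOX2 from 55.1 ± 5.71 to 477 ± 111 CPM (log2 3.11, adjusted p = 0.0022). The sterol-related gene TMEM97 and the retinoic acid-binding protein gene CRABP1 rose by 1.60 and 1.77 on the log2 scale. The giant scaffold gene AHNAK fell from 1290 ± 603 to 366 ± 6.61 CPM (adjusted p = 0.031), the glutamine synthetase gene GLUL from 528 ± 165 to 164 ± 6.08 CPM (adjusted p = 0.028) and GNAS, which encodes a stimulatory G protein subunit, from 300 ± 11.3 to 63.3 ± 14.2 CPM (adjusted p = 0.0067). AHNAK lies on chromosome 11, and GLUL and S100A6 lie on chromosome 1.

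The tests of copy number, of index swapping and of mixed cells below were chosen after the results were seen, and the tests of copy number and of mixed cells were each changed once after a first version had been run. Genes of chromosomes 8, 11 and 1 had medians of -0.42, -0.31 and -0.25 in HER2 L755S cells relative to the other chromosomes. Of 10000 random lists matched on expression, 0 were as low for any of the 3. These 3 were picked for their low medians, and such lists treat genes as independent. The count therefore says nothing about the spread between libraries. The lists were drawn from all chromosomes, the 3 low ones included, while the medians given here are relative to chromosomes other than these 3. That difference lowers the lists against these medians. All 10000 lists were thus as low as chromosomes 2, 6 and 12, with medians of 0.01, 0.02 and 0.03. For chromosomes 15 and 22 (medians -0.05 and -0.07), 3798 and 1531 lists were as low. Removing the trend with GC content or with transcript length left the median closest to 0 of chromosomes 8, 11 and 1 at -0.25. This value argues against both trends as the whole cause. Medians of these chromosomes differed by up to 0.19 in size between libraries of one line, and went with the replicate number in both lines for chromosome 11 (-0.18 and -0.19) and chromosome 8 (0.12 and 0.10), while the differences between the lines were alike in both pairs. On chromosome 19 the difference between numbers was -0.60 in HER2 WT and -0.36 in HER2 L755S cells, yet its difference between the lines was 0.01 (pairs -0.07 and 0.09). Chromosomes 8, 11 and 1 were lower in both pairs (-0.48 and -0.40, -0.33 and -0.32, -0.22 and -0.29), while the other 20 lay between -0.07 and 0.09. Variation that goes with the replicate number cancels within a pair, so it does not account for a shift seen in both pairs. Other variation between libraries stays open. The rule set before the test counted against it only below 0.1, and for it from the smallest shift, 0.25 in size, so 0.19 did not decide. The 3 chromosomes were also picked for their low medians. With 2 libraries a line, the size of that variation is still poorly known. A difference in copy number between the lines may account for the shift, but neither version of its test decides. The chromosome medians nearly fix the share of windows lower in both pairs (58 of 69, 84.1%, against 27.4% elsewhere). The correlation of neighbouring windows was 0.12 (p = 0.1 against 10000 shuffled orders within chromosomes). This correlation cannot show a change of a whole chromosome. A step within a chromosome could raise it, and at that p such a step was neither shown nor excluded. DNA was not analysed here, and the break on chromosome 11, with a median of -0.42 before 85 Mb and 0 beyond, was placed after the values were seen.

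HER2 L755S 1 kept a small share of transcripts that were nearly off in HER2 L755S 2. For 8 genes with at least 300 counts in both HER2 WT libraries and under 2% of HER2 WT 2 in HER2 L755S 2, among them MUC5B, CD74, HLA-DRA and CXCR4, the share of HER2 WT 1 found in HER2 L755S 1 was 4.26% to 11.8%, with a median of 6.85%, and 0 genes met the mirrored rule. Index swapping between libraries sequenced together would move reads both ways, yet 5 genes high in HER2 L755S 1, POSTN, HSD17B2, CLCA2, ABCA12 and ABCC4, had upper 95% limits, which cover counting error only, in HER2 WT 1 below a share of that size even when halved. HER2 WT cells mixed into HER2 L755S replicate 1 may be a source: 3 of 10234 genes with at least 300 counts in HER2 WT 1 (CD74, MUC5B and PHYHD1) had upper limits below the median share in the first version of the test, and 0 did with the limit halved in the second, but CD74 and MUC5B are among the 8 genes that set the median, so neither count decides. Mixed cells and a less complete change of these genes in HER2 L755S 1 cannot be told apart, because a mixed share near the lowest value, 4.04% for PHYHD1, would be possible for all of these 10234 genes.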
